A study of Mus musculus with 52 samples.

How the data were processed

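Hypothalamus, hippocampus and nucleus accumbens of male mice infused with saline or insulin during a clamp were profiled as 52 RNA libraries, in 9 groups of 5 or 6. Per the labels, the libraries were stranded, prepared with a Wafergen kit and sequenced on an Illumina HiSeq instrument. The values used are counts of reads per Ensembl gene, which the authors deposited as 1 table with no normalization. The submitters' processing notes name STAR, an aligner, and featureCounts, a read counter, with the mouse build GRCm38.p4; their versions, options, strand setting and annotation release are not given in the sources used here. Counting reads per gene merges all isoforms, and reads shared between near-identical genes can be lost or split. Genes that overlap on opposite strands cannot be told apart unless the counting used strand, so antisense genes are reported as uncertain. PCR copies of a molecule may be counted more than once, because no molecular identifiers are stated.

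The table holds 46071 genes, of which 14321 have no count in any library. Names came from the GENCODE M21 annotation, which matched 45143 identifiers; the 928 others hold 0.13% of all counts, were kept by identifier and entered the tests. Totals per library ranged from 2453412 to 8279612. Before any averaging, all 125 pairs of libraries within a group were compared with a chi-square test over genes; the statistic per gene ranged from 3.71 to 51.2, so 0 pairs agreed within sampling noise and none was merged as a repeat of the same library. This check does not show that libraries come from separate animals. The titles also carry a tag number for each library; these fall into 3 ranges and into runs of neighbouring numbers, which were treated as possible batches. From the lowest range to the highest, the hypothalamus has 2, 0 and 3 basal, 1, 2 and 3 low, and 0, 2 and 3 high libraries, so the middle range cannot compare insulin with saline there.

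Each tissue was fitted alone with its 3 infusions in edgeR 4.0.16 under R 4.3.3. TMM normalisation was applied, genes with low counts were removed with filterByExpr, and a robust quasi-likelihood model gave 2-sided tests of low minus basal, high minus basal and high minus low. Adjusted p-values follow Benjamini and Hochberg over all genes tested in a contrast, and genes under 0.05 are called. Log2 fold changes and their standard errors come from that model, and CPM values come from edgeR's cpm function with TMM-scaled library sizes. A difference between tissues was tested in 1 model of all 52 libraries as the interaction of tissue and infusion, which takes the libraries as independent; whether tissues came from the same mice is not stated in the labels. Gene lists were tested with camera from limma 3.58.1 on log-CPM values (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, beside camera with an estimated correlation and fry. The 41 lists cover metabolic pathways, neuronal signalling, stress responses and cell types, and 40 had enough members in at least 1 tissue.

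The tests, the 41 lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule takes, per tissue and contrast with basal, up to 5 higher and 5 lower genes with the largest log2 fold change among called genes with a mean CPM of at least 5 and a symbol that is not a predicted gene. Where no gene passed it takes the 3 higher and 3 lower genes with the smallest p, described as not past the threshold. It adds up to 4 members of each list described, the insulin receptor genes Insr, Irs1, Irs2 and Igf1r, 5 genes for each difference between tissues, and 3 and 3 genes between the rates. Lists are described where camera with the preset correlation called them, a choice made after the data were seen, which covers 28 lists and 73 calls. The rule takes 377 pairs of gene and comparison, and the text prints those that it takes by size or smallest p, except some genes that are not reported here, but only part of the list members, picked with their values in view. Sesn3, Ryr3, Cited2 and Txnip, Angptl4 at the low rate in the hypothalamus and Insig1 in the nucleus accumbens lie outside the rule and were chosen after their values were seen.

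Alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma-voom, a threshold of 0.1, the tag range or tag run as a batch term, total count as a covariate, 1 surrogate variable from sva 3.50.0, only the 2 groups compared, all 52 libraries in 1 fit, and leaving out each library in turn. Added after the data were seen were each library's lean to GC-rich and to long transcripts as covariates, a smooth offset for GC and length (loess span 0.3), leaving out GC-leaning libraries (correlation above 0.4), and leaving out hypothalamic libraries in which any of 5 peptide genes is below 1 CPM. The last 2 leave some groups with few libraries.

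The steps were tested on simulated counts drawn from the means and depths of the real libraries, with known changes in a seeded set of genes. In the hypothalamus at the low rate (13983 genes) the test recovered 24% of genes changed 1.5-fold, 82% at 2-fold, 93.9% at 3-fold and 98% at 4-fold, with 8 unchanged genes called. In the hippocampus at the low rate it recovered 20%, 76%, 98% and 93.6%, and in the nucleus accumbens at the low rate 28%, 70%, 93.9% and 96%. The interaction test at the low rate (14509 genes) recovered 15.9%, 59.2%, 88.4% and 92.5%. Changes of 1.5-fold were thus mostly missed at these depths and numbers of libraries, and a gene that was not called is not shown to be unchanged. The simulated genes were drawn independently, so these counts hold no GC lean, batch or difference in dissection. The number of unchanged genes called therefore gives no error rate for the real libraries. In the hypothalamus at the low rate, 1 regrouping of the real libraries other than the labels called 4610 genes.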

Results

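RNA was sequenced from 3 brain regions of 3-month-old male C57BL/6J mice, a common inbred laboratory strain, that had received saline or insulin for 3 h. Infused glucose held their blood glucose steady, a procedure called a clamp. Insulin was given at 4 mU/kg/min, here the low rate, or at 12 mU/kg/min, here the high rate, and saline gave the basal group. The regions were the hypothalamus, which governs feeding and hormone release, the hippocampus, which serves memory, and the nucleus accumbens, the ventral part of the striatum that serves reward. The 52 stranded libraries comprised 5 basal, 6 low and 5 high libraries of the hypothalamus and 6 of each infusion from each of the other regions. Total counts per library ranged from 2453412 to 8279612 with a median of 4654641.5. Group medians lay between 4786650 and 5319913 in the hypothalamus, 4053667 and 4645079 in the hippocampus, and 4258868.5 and 4789474.5 in the nucleus accumbens. The labels tie no library to a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

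Some regional marker genes separated the tissues clearly and others did not. Neurod6, a transcription factor of hippocampal and cortical excitatory neurons, averaged 145 ± 27.8 CPM (normalised counts scaled to library size, SD, n = 18) in the hippocampus and 1.21 in the hypothalamus. In the nucleus accumbens it averaged 4.79 ± 7.75 CPM (SD, n = 18, maximum 24.1). Drd1, the D1 dopamine receptor of striatal projection neurons, averaged 270 ± 80.8 CPM (SD, n = 18) in the nucleus accumbens. Pmch, the precursor of melanin-concentrating hormone made in the lateral hypothalamus, averaged 465 ± 309 CPM (SD, n = 16) in the hypothalamus and 0.451 CPM in the hippocampus. Slc17a7, listed with cortical and hippocampal pyramidal neurons, ranged from 1.64 to 701 CPM in the nucleus accumbens and from 694 to 1820 in the hippocampus. Wfs1, listed as a hippocampal field marker, averaged 593 CPM in the nucleus accumbens and 242 in the hippocampus. Oxt averaged 11.3 CPM (maximum 33) in the nucleus accumbens. In 51 of 52 libraries the marker score of the labelled region was the highest of the 3, low replicate 2 of the hypothalamus being the exception. At least 1 of 5 hypothalamic peptide genes (Hcrt, Pmch, Avp, Oxt and Pomc) was below 1 CPM in 3 of 6 low libraries (replicates 1, 2 and 6) and 2 of 5 high libraries (replicates 3 and 5) of the hypothalamus, and in 0 of 5 basal libraries.

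Libraries also differed in a technical property. In 11 of the 52, genes with GC-rich transcripts were over-represented relative to the mean of their tissue. This means a Spearman correlation above 0.4 across genes, which are not independent replicates, between a library's deviation and transcript GC content. These GC-leaning libraries were 3 of 5 basal libraries (replicates 1, 2 and 5) but 0 of 6 low and 0 of 5 high libraries in the hypothalamus. In the hippocampus they were 1 basal, 2 low and 1 high library, and in the nucleus accumbens 1 basal, 1 low and 2 high libraries. The lean partly followed the tag numbers. In these tissues every library of the lowest tag range leaned (correlation 0.424 to 0.634). Of the hypothalamic libraries in that range, basal replicates 1 and 2 leaned (0.651 and 0.722) and low replicate 1 had 0.302. Basal replicate 5, in the highest range, had 0.444. Basal replicates 3 and 4 of the hypothalamus do not lean (correlation -0.24 and -0.173). A fit without either of these 2 therefore holds a larger share of leaning basal libraries.

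**Figure D1:**
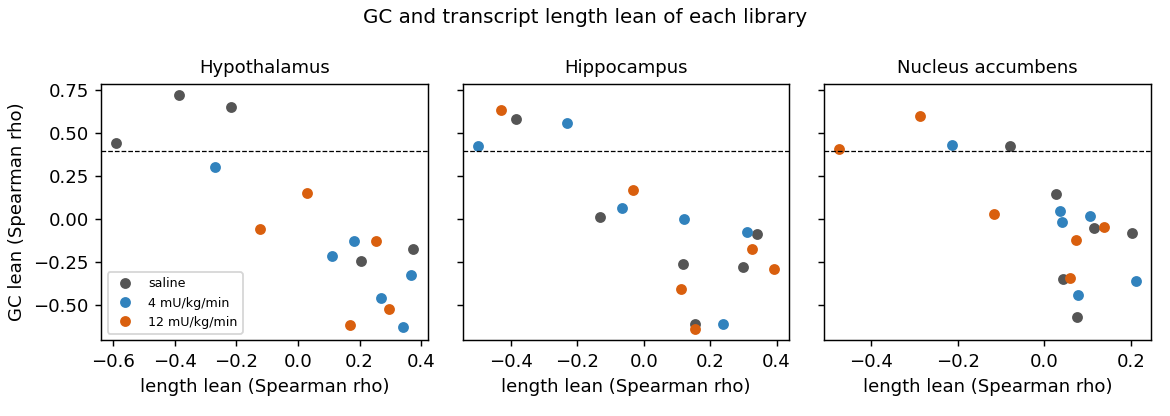
Each point is 1 library, the horizontal axis gives the Spearman correlation across genes of its deviation with transcript length, the vertical axis that with transcript GC content, with colours for saline and the 2 insulin rates and a dashed line at 0.4. In the hypothalamus the 3 points above the line are all saline libraries, whereas in the other tissues each infusion has 1 or 2.

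The first comparison asked which hypothalamic genes differed after insulin at the low rate. Dcc, the netrin receptor that guides growing axons, rose from 2.54 ± 1.22 CPM (SD, n = 5) to 15 ± 3.91 (SD, n = 6), a log2 fold change of 2.67 (SE 0.26, adjusted p = 4.31e-05). All 6 low libraries exceeded every basal library. Zfp871, a zinc-finger protein gene, rose by 3.07 on the log2 scale (SE 0.43, adjusted p = 0.00135), and Lcor, a corepressor of nuclear receptors, by 2.68 (SE 0.37, adjusted p = 0.00135). Lnpep, the insulin-regulated aminopeptidase that travels with glucose transporter vesicles, rose by 3.03 (SE 0.58, adjusted p = 0.0131), from 4.15 ± 2.81 CPM (SD, n = 5) to 30.7 ± 31.2 (SD, n = 6). Low replicate 2 alone had 93.7 CPM (others 12 to 25.5), and without it the log2 fold change of Lnpep was 2.24 (adjusted p = 0.0082). Insig1, which holds the sterol regulator SREBP in the endoplasmic reticulum and is itself an SREBP target, rose from 70.1 ± 6.31 CPM (SD, n = 5) to 114 ± 18.3 (SD, n = 6), a log2 fold change of 0.70 (SE 0.12, adjusted p = 0.00648). It was above every basal library in 6 of 6.

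Chrnb3, a nicotinic acetylcholine receptor subunit, had the largest called change, 4.31 on the log2 scale (SE 1.21, adjusted p = 0.047), but only 4 of 6 low libraries exceeded every basal library, and without low replicate 2 it was 3.40 and not called (adjusted p = 0.103). Among genes that fell, Cited1, a transcriptional co-regulator, changed by -1.52 (SE 0.36, adjusted p = 0.0305), from 26.8 ± 11.2 CPM (SD, n = 5) to 9.58 ± 4.1 (SD, n = 6). Rrad, a small GTPase that restrains calcium channels, changed by -1.40 (SE 0.33, adjusted p = 0.0294) and lay below every basal library in 6 of 6. Tmem158, a membrane protein gene induced by Ras signalling, changed by -1.42 (SE 0.27, adjusted p = 0.0112), and Rprml, a relative of the cell-cycle gene Reprimo, by -1.45 (SE 0.37, adjusted p = 0.0361). Tceal3, of the transcription elongation factor A-like family, changed by -1.26 (SE 0.34, adjusted p = 0.0419), but without the GC-leaning libraries its log2 fold change was 0.05. Angptl4, a fasting-induced inhibitor of lipoprotein lipase, fell from 14.5 ± 3.92 CPM (SD, n = 5) to 6.84 ± 1.37 (SD, n = 6), a log2 fold change of -1.11 (adjusted p = 0.0101).

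In all, edgeR's quasi-likelihood test called 760 of 14139 hypothalamic genes at the low rate, 508 higher and 252 lower (4221 at an unadjusted p under 0.05, where chance gives 707), of which 697 were protein-coding. DESeq2 called 1678 (934 higher, 744 lower), limma-voom 1083 (786 and 297) and 1 fit of all 52 libraries 734 (399 and 335). Without the GC-leaning libraries, a test that left 2 basal libraries, 3 genes were called, namely Dcc, Ryr3 and Sesn3. Of the 760, 754 kept their direction, which is favoured because they were chosen by their change in overlapping libraries. With the range of the library tag number as a batch term 29 were called (27 higher, 2 lower), with the run of neighbouring tags 16 (15 and 1), and without the libraries lacking a peptide 24 (24 and 0). Higher and lower calls were 89 and 3 with the lean of each library as a covariate, 345 and 46 with 1 surrogate variable, 94 and 32 with a GC and length offset, and 22 and 0 with only the 2 groups compared. Leaving out 1 library moved the count to 92, 52, 2567, 3171 or 197 without basal replicate 1, 2, 3, 4 or 5, and to 2034, 120, 136, 222, 477 or 138 without low replicate 1, 2, 3, 4, 5 or 6. The highest counts, 2567 and 3171, came without a basal library that does not lean to GC-rich transcripts. Of the named called genes, Dcc, Zfp871, Lcor, Tmem158, Insig1 and Kcnma1 passed in each of those 11 fits. The other 16 lost their call in 1 (Lnpep) to 8 of the 11 fits, among them Rictor, Sc5d, Tceal3, Rps3 and Ugt8a in 8 and Cited1, Rprml, Vgf and Gjc3 in 7. Of the 22, those lost were 14, 16 and 13 without basal replicate 1, 2 or 5, and 14, 13, 9, 5 and 14 without low replicate 2, 3, 4, 5 or 6, with the highest adjusted p without basal replicate 2 (0.061 for Stard4 to 0.162 for Ugt8a).

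**Figure D2:**
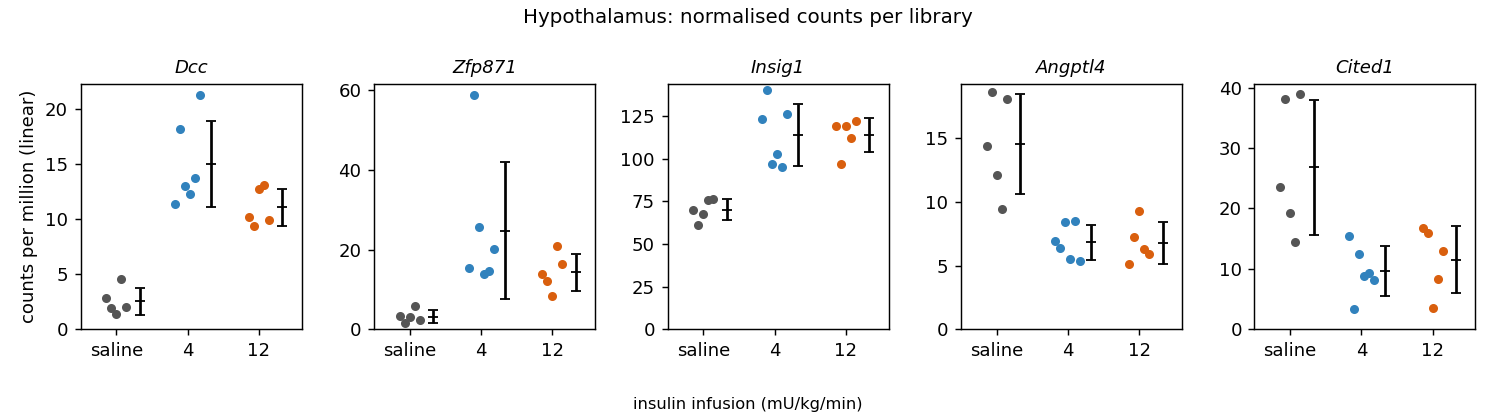
CPM of Dcc, Zfp871, Insig1, Angptl4 and Cited1 in the hypothalamus for saline and insulin at 4 and 12 mU/kg/min, where each point is 1 library and bars give the mean and SD of 5, 6 and 5 libraries. All 6 low and all 5 high libraries lie above every saline library for Dcc and Insig1.

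Gene lists fixed beforehand were then tested against all other genes with camera at a preset inter-gene correlation. Of the 5 basal libraries to which each hypothalamic list was compared, 3 leaned to GC-rich transcripts. Genes of cholesterol synthesis and uptake were higher at the low rate, with 13 of 24 measured members above 0 and a median log2 fold change of 0.18 (adjusted p = 0.016). With an inter-gene correlation estimated from the data instead, here the estimated-correlation adjusted p, 0 lists of any comparison passed, and this one had adjusted p = 0.24 with an estimated correlation. Of the cholesterol genes 4 rose and 0 fell over all genes tested, and 8 rose and 0 fell adjusted over the list alone. Beside Insig1 they were Stard4, a cytosolic sterol carrier (log2 fold change 0.69, adjusted p = 0.0138), Hsd17b7, a late enzyme of the pathway (0.85, adjusted p = 0.0373), and Sc5d, a sterol desaturase (0.59, adjusted p = 0.0455). Fry, which tests the list by itself, gave an adjusted p of 0.00524. The list was no longer called without the libraries lacking a peptide (adjusted p = 0.135).

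Potassium and HCN channel genes, which set neuronal excitability, were higher (median 0.29, 28 of 43 above 0, adjusted p = 0.0105, estimated-correlation adjusted p = 0.933), with 2 higher and 0 lower over all genes and 10 and 1 adjusted over the list alone. Kcnma1, the large-conductance calcium-activated channel, rose by 1.71 (adjusted p = 0.00293) and Kcna2, a delayed rectifier of axons, by 0.81 (adjusted p = 0.0232). Insulin and IGF signalling genes had a median of 0.22 (20 of 30 above 0, adjusted p = 0.0379, estimated-correlation adjusted p = 0.933), and the list turned to lower without the GC-leaning libraries (adjusted p = 0.705). Its call also ended with 1 surrogate variable (adjusted p = 0.327) and with the lean of each library as a covariate (adjusted p = 0.0537). Of its members 1 rose over all genes, and 9 were higher and 1 lower adjusted over the list alone. That member was Rictor, a core part of mTOR complex 2 (0.86, adjusted p = 0.0351), and Pik3ca, a catalytic subunit of PI3-kinase, had 0.42 (adjusted p = 0.0592). Pik3ca passed without basal replicate 3 or 4, which do not lean to GC-rich transcripts, or low replicate 1 (adjusted p = 0.0334, 0.0167 and 0.0447). Oligodendrocyte markers had a median of 0.38 with 12 of 13 above 0 (adjusted p = 0.0105, estimated-correlation adjusted p = 0.933), 2 higher over all genes and 5 adjusted over the list alone. Those were Gjc3, a glial connexin (0.60, adjusted p = 0.0419), and Ugt8a, which makes myelin galactolipids (0.85, adjusted p = 0.0473).

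Neuropeptide genes were lower at the low rate (median -0.66, 21 of 25 below 0, adjusted p = 0.000608, estimated-correlation adjusted p = 0.933), with 1 lower over all genes and 8 adjusted over the list alone. Vgf, a precursor of secreted peptides, fell (-0.65, adjusted p = 0.0328). Pomc, the melanocortin precursor of satiety neurons, averaged 5.3 ± 3.24 CPM (SD, n = 6) against 20.2 ± 8.41 (SD, n = 5), with 6 of 6 libraries below every basal one. It did not pass the threshold (-1.95, adjusted p = 0.0641). Nor did Trh, thyrotropin-releasing hormone (-1.58, adjusted p = 0.0627), or Sst, somatostatin (-1.31, adjusted p = 0.0527). Without basal replicate 3 or 4, which do not lean to GC-rich transcripts, these 3 genes passed (adjusted p = 0.0459 and 0.0365 for Pomc, 0.0368 and 0.0315 for Trh, 0.0264 and 0.0132 for Sst). Hypothalamic region markers, which share some of these genes, had a median of -1.54 (12 of 14 below 0, adjusted p = 0.00786, estimated-correlation adjusted p = 0.933), 0 called over all genes and 5 lower adjusted over the list alone. The libraries lacking a peptide were all in the insulin groups, 3 of 6 low and 2 of 5 high. Ependymal and tanycyte markers, of cells lining the ventricle, had a median of -0.81 with 8 of 8 below 0 (adjusted p = 0.00786, estimated-correlation adjusted p = 0.933), 1 lower over all genes and 6 adjusted over the list alone. Ccdc153, a gene of ciliated cells, was the one that fell (-1.57, adjusted p = 0.0294), and Vim, an intermediate filament of tanycytes, had -0.40 (adjusted p = 0.0879), a value that passed without basal replicate 4 (adjusted p = 0.0496) or low replicate 1 (adjusted p = 0.0487). Ribosomal protein genes had a median of -0.64 with 50 of 50 below 0 (adjusted p = 6.47e-05, estimated-correlation adjusted p = 0.947), 1 lower over all genes (Rps3, -0.90, adjusted p = 0.0455) and 0 adjusted over the list alone. That direction turned without the GC-leaning libraries (adjusted p = 0.000176, Rps3 0.03) and with 1 surrogate variable (adjusted p = 0.974), and the call ended with the lean as a covariate (adjusted p = 0.604). Without the libraries lacking a peptide the hypothalamic region markers (adjusted p = 0.112) and the oligodendrocyte list (adjusted p = 0.779) were no longer called, whereas neuropeptide genes (adjusted p = 0.00822) and ependymal markers (adjusted p = 0.0161) were. Leaving out the GC-leaning libraries ended the calls of potassium channel (adjusted p = 0.265), neuropeptide (adjusted p = 0.14) and ependymal genes (adjusted p = 0.287).

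At the high rate the hypothalamus showed fewer called genes, led by some of the same ones. Dcc rose to 11.1 ± 1.69 CPM (SD, n = 5), a log2 fold change of 2.24 (SE 0.26, adjusted p = 0.000562), above every basal library in 5 of 5. Zfp871 rose by 2.28 (SE 0.44, adjusted p = 0.0369), Lcor by 1.99 (SE 0.39, adjusted p = 0.0369), and Cbl, a ubiquitin ligase that acts on receptor tyrosine kinases, by 1.91 (SE 0.34, adjusted p = 0.0188). Insig1 rose to 114 ± 10.2 CPM (SD, n = 5), a log2 fold change of 0.71 (SE 0.12, adjusted p = 0.0158), in 5 of 5 libraries above every basal one. Srrm4os, transcribed antisense to the splicing regulator Srrm4, rose by 1.87 (SE 0.27, adjusted p = 0.00302), an uncertain assignment since the strand setting of the counting is not stated. Angptl4 was the only gene called lower, at 6.76 ± 1.62 CPM (SD, n = 5), a log2 fold change of -1.11 (SE 0.21, adjusted p = 0.0369), with 5 of 5 libraries below every basal one.

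The quasi-likelihood test of edgeR called 26 of 14139 genes at the high rate, 25 higher and 1 lower (3406 at an unadjusted p under 0.05, where chance gives 707), of which 16 were protein-coding. By contrast, DESeq2 called 359 (257 higher, 102 lower) and limma-voom 53 (50 and 3). Without the GC-leaning libraries 1 gene was called (Sesn3), with the tag range as a batch term 5, with the tag run 0, without the libraries lacking a peptide 9, and in 1 fit of all 52 libraries 0. Leaving out 1 library moved the count to 14, 6, 613 or 1861 without basal replicate 1, 2, 3 or 4, and to 15, 10 or 17 without high replicate 1, 4 or 5. Dcc and Srrm4os passed in each of the 10 leave-one-out fits, whereas Zfp871, Lcor and Angptl4 lost their calls in 7 of them, Insig1 in 5 and Cbl in 4. All 5 were lost without basal replicate 1 or 2 or high replicate 4, 3 or 4 of them without basal replicate 5 or high replicate 1, 2 or 5, and Cbl without high replicate 3, with the highest adjusted p without basal replicate 2 (0.107 for Insig1 to 0.185 for Zfp871).

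The cholesterol list was again higher at the high rate (median 0.11, 16 of 24 above 0, adjusted p = 0.019, estimated-correlation adjusted p = 0.153, fry adjusted p = 0.0102). Only Insig1 rose over all genes, and 10 rose adjusted over the list alone. Stard4 had 0.58 (adjusted p = 0.0835). Potassium and HCN channel genes had a median of 0.23 (28 of 43 above 0, adjusted p = 0.0255, estimated-correlation adjusted p = 0.691), with 0 called over all genes and 1 higher adjusted over the list alone. Kcnma1 had 1.25 (adjusted p = 0.0634). GABA receptor genes, encoding the main inhibitory receptors, had a median of 0.23 (12 of 16 above 0, adjusted p = 0.028, estimated-correlation adjusted p = 0.691), 0 called over all genes and 1 higher adjusted over the list alone. Gabrb2 had 1.28 (adjusted p = 0.0673). Insulin and IGF signalling genes had a median of 0.17 (21 of 30 above 0, adjusted p = 0.0433, estimated-correlation adjusted p = 0.691) with 0 called either way, and the list turned to lower without the GC-leaning libraries (adjusted p = 0.564). With 1 surrogate variable the calls of insulin (adjusted p = 0.6), GABA receptor (adjusted p = 0.231) and potassium channel genes (adjusted p = 0.13) ended, and with the lean as a covariate that of GABA receptors (adjusted p = 0.38). Without basal replicate 3 or 4, which do not lean to GC-rich transcripts, Stard4 (adjusted p = 0.0466 and 0.0161), Kcnma1 and Gabrb2 (0.0466 and 0.00842 for both) passed. Gabrb2 also passed without basal replicate 5, which does lean (adjusted p = 0.0243).

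Of the lists lower at the high rate, ribosomal protein genes had a median of -0.55 (49 of 50 below 0, adjusted p = 0.000333, estimated-correlation adjusted p = 0.691). Nuclear genes of the respiratory chain had -0.47 (43 of 46 below 0, adjusted p = 0.019, estimated-correlation adjusted p = 0.694). In both, 0 members were called over all genes or adjusted over the list alone. Rps3 had -0.78 (adjusted p = 0.143) and Ndufs7, a complex I subunit, -1.24 (adjusted p = 0.144). Both lists turned to higher without the GC-leaning libraries (adjusted p = 2.24e-08 and 5.79e-09) and with 1 surrogate variable (adjusted p = 0.0778 and 0.00254). Glycolysis genes had a median of -0.28 (17 of 21 below 0, adjusted p = 0.019, estimated-correlation adjusted p = 0.691), 0 called over all genes and 2 lower adjusted over the list alone. They too turned to higher without those libraries (adjusted p = 0.949). Pfkl, the liver-type phosphofructokinase, had -0.81 (adjusted p = 0.107) and Gpi1, glucose-6-phosphate isomerase, -0.51 (adjusted p = 0.118). Neuropeptide genes had a median of -0.51 (20 of 25 below 0, adjusted p = 0.019, estimated-correlation adjusted p = 0.691), with 0 called over all genes or adjusted over the list alone. Vgf was at -0.60 (adjusted p = 0.113), Trh at -1.14 (adjusted p = 0.189) and Sst at -0.88 (adjusted p = 0.191). Ependymal and tanycyte markers had a median of -0.50 (7 of 8 below 0, adjusted p = 0.0306, estimated-correlation adjusted p = 0.691), 0 called over all genes and 2 lower adjusted over the list alone. The calls of ependymal and potassium channel genes ended without the libraries lacking a peptide (adjusted p = 0.0539 for each), and those of glycolysis (adjusted p = 0.108) and ependymal genes (adjusted p = 0.105) with the tag run as a block. Leaving out the GC-leaning libraries ended those of GABA receptor (adjusted p = 0.707), potassium channel (adjusted p = 0.589), neuropeptide (adjusted p = 0.99) and ependymal genes (adjusted p = 0.803). With 1 surrogate variable the glycolysis (adjusted p = 0.214), neuropeptide (adjusted p = 0.117) and ependymal calls (adjusted p = 0.147) ended. With the lean as a covariate these 3 (adjusted p = 0.615, 0.0521 and 0.069), the respiratory chain (adjusted p = 0.632) and the ribosomal call (adjusted p = 0.204) ended, and with the tag range those of glycolysis (adjusted p = 0.0795) and ependymal genes (adjusted p = 0.0651). Single genes of these lists passed without basal replicate 3 or 4, namely Rps3 (adjusted p = 0.0498 and 0.0252), Pfkl (0.0466 and 0.0148), Gpi1 (0.0466 and 0.0211) and Vgf (0.0428 and 0.0276), and Ndufs7 without basal replicate 4 (0.038). Neither of these basal libraries leans to GC-rich transcripts, so the leaning ones weighed more in those fits.

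Between the 2 insulin rates edgeR, DESeq2 and limma-voom each called 0 hypothalamic genes, and 199 had an unadjusted p under 0.05 where chance gives 707. Crym, a thyroid hormone binding protein of tanycytes, had 1.40 (high minus low), Ngfr, the p75 neurotrophin receptor, 1.27, and Sh2d5, an SH2-domain adaptor, 0.34. Prkd2, a diacylglycerol-activated kinase, had -0.74, Icam1, an adhesion molecule of activated endothelium, -1.25, and Cp, ceruloplasmin, -0.76 (adjusted p = 1 for all 6). Without high replicate 3, one of the libraries lacking a peptide, Crym had 0.70 and Ngfr 0.52. Neuropeptide genes (median 0.43, adjusted p = 0.0037, estimated-correlation adjusted p = 0.517) and hypothalamic region markers (0.46, adjusted p = 0.000812, estimated-correlation adjusted p = 0.442) were higher at the high rate. Lists of other cell types were lower: oligodendrocytes (median -0.34, adjusted p = 1.73e-06), microglia (-0.16, adjusted p = 0.00587), thalamus (-0.40, adjusted p = 0.000427) and meninges (-0.58, adjusted p = 0.000837), each with estimated-correlation adjusted p = 0.442. So were endothelial cells (-0.22, adjusted p = 5.24e-06, estimated-correlation adjusted p = 0.278), mural cells (-0.49, adjusted p = 0.000837, estimated-correlation adjusted p = 0.4) and blood cells (-1.30, adjusted p = 0.000427, estimated-correlation adjusted p = 0.4). The blood genes depended on single libraries. Without low replicate 2 Hba-a1 went from -1.56 to -0.64 and Hbb-bs from -0.84 to -0.23, and without high replicate 5 Hbb-bs went to -1.67. In these 9 lists 0 members were called over all genes and 0 adjusted over the list alone. Of the libraries compared, 3 of 6 low and 2 of 5 high lacked a hypothalamic peptide, and without them 0 of the 9 lists were called (adjusted p from 0.053 for meninges to 0.973 for thalamus).

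All 26 genes called at the high rate were also called at the low rate in the same direction, 25 higher and 1 lower, where independent lists of those sizes share 0.898 and 0.0178. The 2 comparisons use the same basal libraries. In 20 simulations of unchanged groups against those libraries almost no gene was called (at the high rate a mean of 0.05 higher and 0.15 lower, at the low rate 0), so they give no chance level for shared calls. Log2 fold changes of all genes correlated across genes, which are not independent replicates, at r = 0.892 (covariance 0.163), against 0.526 (0.0315) in the simulations. The simulations drew genes independently, without the GC lean, so set no level for r. With basal libraries split between the comparisons, 20 splits gave medians of 3 shared calls (range 0 to 16) and r = 0.554 (covariance 0.146). Both parts can hold leaning libraries, so a shared lean can stay.

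In the hippocampus at the low rate the clearest differences lay in oligodendrocyte markers, although no single gene passed the threshold. Of 13 measured markers 13 were above 0, with a median log2 fold change of 0.89 (adjusted p = 7.09e-24, estimated-correlation adjusted p = 0.0581, fry adjusted p = 0.0245). None was called over all genes and 13 rose adjusted over the list alone. Mal, a proteolipid of compact myelin, averaged 311 ± 97.5 CPM (SD, n = 6) against 167 ± 23.2 (SD, n = 6) in basal libraries, a log2 difference of 0.89 (SE 0.16, adjusted p = 0.156), above every basal library in 6 of 6. Mbp, myelin basic protein, averaged 3890 ± 2570 CPM (SD, n = 6) against 1850 ± 439 (SD, n = 6), a log2 difference of 1.07 (adjusted p = 0.255). Low replicate 5 alone had 9100 CPM of Mbp (others 2610 to 3420), and without it the log2 difference was 0.63 (adjusted p = 0.372). Mobp, another myelin protein gene, had 0.99 (adjusted p = 0.187). Adamts4, a matrix protease, had 0.90 (adjusted p = 0.156). Lower values were found for Bhlhe22, a transcription factor of excitatory neurons (-0.45, adjusted p = 0.21), Fam163b (-0.40, adjusted p = 0.293) and Adamts17 (-0.64, adjusted p = 0.293).

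Lipid synthesis genes were also higher there. Of 24 cholesterol genes 20 were above 0 (median 0.21, adjusted p = 0.000123, estimated-correlation adjusted p = 0.13), with 0 called over all genes and 2 higher adjusted over the list alone. Insig1 averaged 55.9 ± 9.22 CPM (SD, n = 6) against 36.9 ± 3.62 (SD, n = 6), a log2 difference of 0.60 (adjusted p = 0.183). It was above every basal library in 6 of 6 low libraries. Of 18 fatty acid synthesis genes 16 were above 0 (median 0.13, adjusted p = 0.000431, estimated-correlation adjusted p = 0.0757), with 0 called over all genes. Scd2, a brain stearoyl-CoA desaturase, had 0.31 (adjusted p = 0.533). Glucocorticoid-responsive genes had a median of 0.29 (16 of 17 above 0, adjusted p = 2.66e-05, estimated-correlation adjusted p = 0.369), 0 called over all genes and 5 higher adjusted over the list alone. Among them were Arrdc2, an arrestin-domain gene (1.19, adjusted p = 0.285), Plin4, a lipid droplet protein (0.91, adjusted p = 0.348), and Sgk1, a serum- and glucocorticoid-regulated kinase (0.65, adjusted p = 0.354). Unfolded protein response genes had a median of 0.20 (17 of 18 above 0, adjusted p = 0.00473, estimated-correlation adjusted p = 0.432). Respiratory chain genes had 0.15 (adjusted p = 0.0167, estimated-correlation adjusted p = 0.653) and ribosomal protein genes 0.12 (adjusted p = 0.0104, estimated-correlation adjusted p = 0.653). Sodium and calcium channel genes had -0.09 (adjusted p = 0.0254, estimated-correlation adjusted p = 0.475). In the fatty acid list and these last 4 lists 0 members were called adjusted over the list alone. With 1 surrogate variable the respiratory chain (adjusted p = 0.773), ribosomal (adjusted p = 0.836) and channel calls (adjusted p = 0.0755) ended, and with the lean as a covariate the respiratory chain (adjusted p = 0.0801) and ribosomal calls (adjusted p = 0.0685).

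Markers of tissue next to the hippocampus were higher as lists in the same comparison, but their scores per library did not separate the groups. The choroid plexus score was above every basal library in 4 of 6 low libraries (difference 1.68 on the log2 scale, two-sided exact permutation p = 0.115, adjusted over 8 tests 0.184) and the ependymal score in 4 of 6 (0.83, exact permutation p = 0.0541, adjusted 0.143). The thalamic score was above in 1 of 6 (0.27, exact permutation p = 0.526, adjusted 0.526). Choroid plexus markers, of the epithelium in the ventricles, had a median of 1.81 (10 of 10 above 0, adjusted p = 1.11e-05, estimated-correlation adjusted p = 0.462). Folr1, a folate receptor, averaged 22.9 ± 23.4 CPM against 3.82 ± 4.77 (log2 difference 2.56, adjusted p = 0.765), and Kcnj13, a potassium channel, had 2.32 (adjusted p = 0.748). Without basal replicate 6 these were 3.57 and 3.68, and without low replicate 6 Folr1 had 1.95. Ependymal markers had 1.16 (5 of 6 above 0, adjusted p = 0.000916, estimated-correlation adjusted p = 0.311), 0 called over all genes and 4 higher adjusted over the list alone. Foxj1, the regulator of motile cilia, had 1.78 (adjusted p = 0.278). Meningeal markers had 0.89 (adjusted p = 0.00797, estimated-correlation adjusted p = 0.475) and oligodendrocyte precursor markers 0.27 (adjusted p = 0.00691, estimated-correlation adjusted p = 0.311). Markers of hippocampal fields were lower (median -0.28, 8 of 8 below 0, adjusted p = 0.00432, estimated-correlation adjusted p = 0.255). Examples are Dsp, a desmosomal protein of dentate granule cells (-0.55, adjusted p = 0.668), and Calb1, the calcium buffer calbindin (-0.41, adjusted p = 0.765). Adjusted over the list alone, 1 precursor marker was higher, and 0 choroid plexus, meningeal or field markers were called. Here 2 low libraries and 1 basal library leaned to GC-rich transcripts. Without the GC-leaning libraries of this tissue the ependymal (adjusted p = 0.468), meningeal (adjusted p = 0.473), sodium and calcium channel (adjusted p = 0.473), unfolded protein and respiratory chain lists (adjusted p = 0.07 for both) were no longer called, and the channel list was also lost with the tag run as a block (adjusted p = 0.0562). By edgeR 0 of 13515 genes were called (817 at an unadjusted p under 0.05, where chance gives 676, smallest adjusted p 0.156), by limma-voom 0 and by DESeq2 38. All 52 libraries in 1 fit gave 101, and the lean of each library as a covariate 17.

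**Figure D3:**
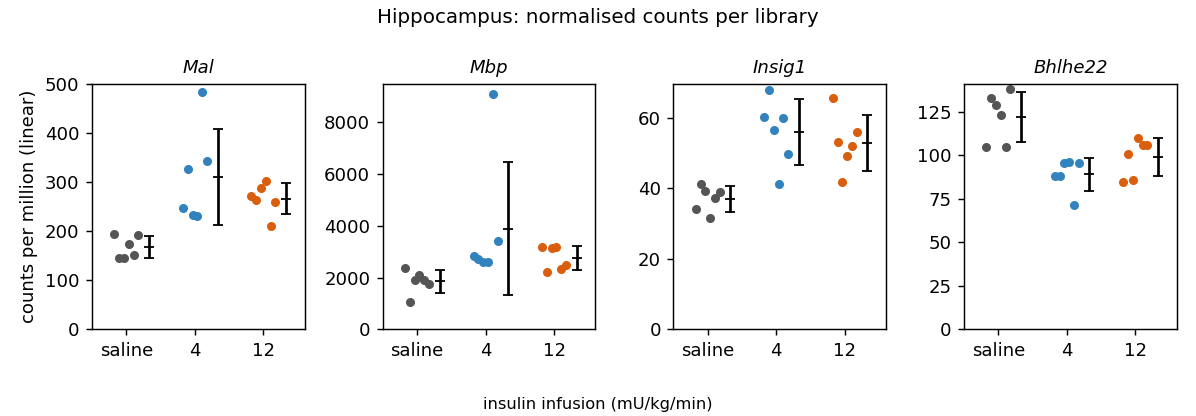
CPM of Mal, Mbp, Insig1 and Bhlhe22 in the hippocampus for saline and insulin at 4 and 12 mU/kg/min, where each point is 1 library and bars give the mean and SD of 6 libraries per infusion. All 6 low libraries lie above every saline library for Mal, Mbp and Insig1 and below every one for Bhlhe22, though no gene passed the threshold over all genes.

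At the high rate hippocampal oligodendrocyte markers were again higher as a list, with 13 of 13 above 0 and a median of 0.58 (adjusted p = 1.31e-20, estimated-correlation adjusted p = 0.102, fry adjusted p = 0.387). None was called over all genes and 2 were higher adjusted over the list alone. Mal averaged 266 ± 31.7 CPM (SD, n = 6, log2 difference 0.67) and Opalin, a myelin sialoglycoprotein, 9.25 ± 1.77 (1.05). Insig1 averaged 52.8 ± 7.9 CPM (SD, n = 6, 0.52) and exceeded every basal library in 6 of 6, and Dcc averaged 10 ± 10.1 against 2.04 ± 0.495 CPM (SD, n = 6, 2.33). Bhlhe22 had -0.31, Paqr7, a membrane progestin receptor, -0.33, and Sybu, which links vesicles to kinesin, -0.28. The adjusted p was 1 for each of these genes. Cholesterol genes (median 0.08, 20 of 24 above 0, adjusted p = 0.00283, estimated-correlation adjusted p = 0.355, 1 higher adjusted over the list alone) were higher. So were fatty acid synthesis genes (0.10, adjusted p = 0.00529, estimated-correlation adjusted p = 0.247) and glucocorticoid-responsive genes (0.15, adjusted p = 0.00283, estimated-correlation adjusted p = 0.568). Inflammation genes were higher as well (0.25, 11 of 12 above 0, adjusted p = 0.00283, estimated-correlation adjusted p = 0.486), with C3, a complement component, at 1.49 (adjusted p = 1). Choroid plexus (1.26, adjusted p = 0.00416, estimated-correlation adjusted p = 0.783) and ependymal markers (0.26, adjusted p = 0.0377, estimated-correlation adjusted p = 0.568) were higher too. Their scores were above every basal library in 2 and 4 of 6 high libraries (exact permutation p = 0.383 and 0.0714, adjusted 0.438 and 0.143). Without high replicate 5 Aqp1 went from 1.87 to 0.35, Folr1 from 1.83 to 0.33, Kcnj13 from 1.53 to 0.47 and Sostdc1 from 0.99 to -0.03. Without basal replicate 6 the first 3 were 2.72, 2.84 and 2.88. Immediate early genes, which mark recent neuronal activity, were lower (median -0.11, 16 of 19 below 0, adjusted p = 0.00939, estimated-correlation adjusted p = 0.568), with Dusp6, a phosphatase of ERK, at -0.36 (adjusted p = 1). Except where given, 0 members of these lists were called adjusted over the list alone. The calls of cholesterol (adjusted p = 0.156) and ependymal genes (adjusted p = 0.216) ended without the GC-leaning libraries, the latter also with the tag run as a block (adjusted p = 0.0591), with 1 surrogate variable (adjusted p = 0.0917) and with the lean as a covariate (adjusted p = 0.0656), which ended the choroid plexus call too (adjusted p = 0.051). By edgeR, DESeq2 and limma-voom 0 genes were called, with 353 at an unadjusted p under 0.05.

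Between the rates in the hippocampus 0 genes were called by edgeR, DESeq2 and limma-voom (384 at an unadjusted p under 0.05). Xkr4 (1.81, high minus low), Dgkh, a diacylglycerol kinase (1.55), Zfp871 (2.42), Kdr, the VEGF receptor of endothelium (-0.64), and Tac2, the neurokinin B precursor (-2.57), had adjusted p = 1. Field markers were higher at the high rate (median 0.36, 8 of 8 above 0, adjusted p = 0.00088, estimated-correlation adjusted p = 0.245). Unfolded protein response genes were lower with 18 of 18 below 0 (median -0.27, adjusted p = 1.1e-06, estimated-correlation adjusted p = 0.245). Thalamic markers were lower as well (median -0.86, adjusted p = 0.000344, estimated-correlation adjusted p = 0.467, 3 lower adjusted over the list alone). Much of this came from low replicate 2, whose thalamic score was 6.47 against 4.39 to 5.15 in the other low libraries. Without it Tcf7l2 went from -2.08 to -0.90, Prkcd from -1.13 to -0.56, Synpo2 from -1.09 to -0.29 and Amotl1 from -0.98 to -0.52. Oligodendrocyte (-0.36, adjusted p = 0.000344, estimated-correlation adjusted p = 0.497) and choroid plexus markers (-0.74, adjusted p = 0.0198, estimated-correlation adjusted p = 0.541) were lower too. Single libraries moved choroid plexus genes in both directions. Without high replicate 5 Kcnj13 went from -0.80 to -1.87, Kcne2 from -0.98 to -1.71 and Otx2 from -0.75 to -1.57. Ttr went from -1.11 to -0.47 without low replicate 6 and to -1.77 without high replicate 3. Ribosomal protein genes had -0.04 (adjusted p = 0.0119, estimated-correlation adjusted p = 0.664), a direction that turned with 1 surrogate variable (adjusted p = 0.895). Respiratory chain genes, neuropeptides, oligodendrocyte precursors and endothelial, mural and blood cell markers were also lower (adjusted p from 0.000344 to 0.0345, estimated-correlation adjusted p from 0.437 to 0.555). Beyond the thalamic markers, 1 neuropeptide gene was lower and 0 others were called adjusted over the list alone. Oligodendrocyte (adjusted p = 0.311), precursor (adjusted p = 0.0626) and choroid plexus markers (adjusted p = 0.952) were no longer called without the GC-leaning libraries, nor choroid plexus markers with the tag run as a block (adjusted p = 0.0689). Respiratory chain, neuropeptide and precursor calls ended with 1 surrogate variable (adjusted p = 0.593, 0.426 and 0.111) and with the lean as a covariate (adjusted p = 0.341, 0.341 and 0.122), the latter also ending the ribosomal call (adjusted p = 0.717).

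In the nucleus accumbens no gene passed the threshold at either rate. At the low rate Lyrm2, a mitochondrial LYR-motif protein, had 0.67, Ccdc159 0.41 and Cth, cystathionine gamma-lyase, 0.58 on the log2 scale. Fcgr3, an immunoglobulin receptor of microglia, had -0.59, Angptl4 -0.77 (6 ± 2.04 CPM, SD, n = 6, against 10.5 ± 3.83) and Nfkbib, an inhibitor of NF-kappaB, -0.45, with adjusted p = 1 for each. Genes of dopamine and striatal signalling were higher as a list (median 0.27, 13 of 16 above 0, adjusted p = 0.0331, estimated-correlation adjusted p = 0.775), with 0 called over all genes or adjusted over the list alone. That call ended without the GC-leaning libraries (adjusted p = 0.15) and with the lean of each library as a covariate (adjusted p = 0.0711). Gpr6, a receptor of striatopallidal neurons, had 0.50 and Pde10a, the striatal phosphodiesterase, 0.45, while Th, the dopamine-synthesising hydroxylase of afferent axons, had -0.57 (adjusted p = 1 for each). Insig1 averaged 66.8 ± 13.5 CPM (SD, n = 6) at the low and 68.3 ± 10.5 at the high rate against 61.8 ± 7.95 (log2 differences of 0.12 and 0.14, adjusted p = 1).

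At the high rate in the nucleus accumbens Morn2, a gene of ciliated and germ cells, had 1.03 (9.66 ± 3.57 CPM against 4.53 ± 1.52), Ttn, titin, 1.07 and Trmt12, a tRNA-modifying enzyme, 0.69. Adgrl4, an adhesion receptor of endothelium, had -0.62, Pde3b, an insulin-activated phosphodiesterase, -0.47 and Fggy, a carbohydrate kinase, -0.52 (adjusted p = 1 for each). Respiratory chain genes were higher with 39 of 46 above 0 (median 0.19, adjusted p = 1.72e-08, estimated-correlation adjusted p = 0.479), led by Uqcr11, a complex III subunit (0.47). Ribosomal protein genes were higher with 43 of 50 above 0 (0.15, adjusted p = 1.17e-06, estimated-correlation adjusted p = 0.705), with Rps21 at 0.51, and they turned to lower with the lean of each library as a covariate (adjusted p = 0.876). Glycolysis (0.11, adjusted p = 0.0428, estimated-correlation adjusted p = 0.831), cholesterol (0.06, adjusted p = 0.0428, estimated-correlation adjusted p = 0.756), dopamine (0.20, adjusted p = 0.0318, estimated-correlation adjusted p = 0.831) and heat shock genes (0.16, adjusted p = 0.0318, estimated-correlation adjusted p = 0.479) were higher. Endothelial markers were lower with 11 of 12 below 0 (-0.21, adjusted p = 1.78e-05, estimated-correlation adjusted p = 0.479), including Ly6c1 (-0.32) and Abcb1a, the P-glycoprotein pump of the blood-brain barrier (-0.36). In these lists 0 members were called over all genes or adjusted over the list alone, and 1 basal and 2 high libraries leaned to GC-rich transcripts. Without the GC-leaning libraries the glycolysis (adjusted p = 0.801), cholesterol (adjusted p = 0.646), dopamine (adjusted p = 0.169) and heat shock lists (adjusted p = 0.223) were no longer called. With the lean as a covariate the respiratory chain (adjusted p = 0.395), glycolysis (adjusted p = 0.831), cholesterol (adjusted p = 0.416) and heat shock calls (adjusted p = 0.508) ended, and that of cholesterol genes also with the tag range (adjusted p = 0.0515) and with the tag run as a block (adjusted p = 0.0566).

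Between the rates in the nucleus accumbens respiratory chain (median 0.18, adjusted p = 2.22e-08, estimated-correlation adjusted p = 0.502), ribosomal protein (0.15, adjusted p = 2.49e-07, estimated-correlation adjusted p = 0.655) and glycolysis genes (0.11, adjusted p = 0.0206, estimated-correlation adjusted p = 0.655) were higher at the high rate. Immediate early genes (-0.24, adjusted p = 0.0223, estimated-correlation adjusted p = 0.949), endothelial (-0.25, adjusted p = 2.57e-06, estimated-correlation adjusted p = 0.502) and mural cell markers (-0.32, adjusted p = 0.00727, estimated-correlation adjusted p = 0.607) were lower. In these lists 0 members were called over all genes or adjusted over the list alone. With the lean as a covariate the respiratory chain (adjusted p = 0.137), ribosomal (adjusted p = 0.888), glycolysis (adjusted p = 0.593) and immediate early gene calls (adjusted p = 0.685) ended, the last 2 also without the GC-leaning libraries (adjusted p = 0.388 and 0.0567). Ttn (1.03), Ppfibp2, a liprin scaffold (0.64), Wdr55 (0.65), Fndc3b (-0.34), Eif4ebp2, a translation repressor (-0.44), and Cfap65, a sperm flagellum gene (-0.69), had adjusted p = 0.999. For the low, high and between-rate comparisons edgeR, DESeq2 and limma-voom called 0 of 13769 genes, with 196, 326 and 292 at an unadjusted p under 0.05 where chance gives 688.

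The receptors and adaptors of insulin itself did not pass the threshold in any tissue with all libraries. In the hypothalamus Insr, the insulin receptor, averaged 144 ± 14.9 CPM (SD, n = 6) at the low rate against 103 ± 37.3 (SD, n = 5), a log2 difference of 0.49 (adjusted p = 0.0913). At the high rate it had 0.39 (adjusted p = 0.208). Igf1r, the IGF-1 receptor, had 0.51 and 0.29 (adjusted p = 0.11 and 0.373), and the adaptors Irs1 0.47 and 0.45 (adjusted p = 0.211 and 0.273) and Irs2 -0.21 and -0.06 (adjusted p = 0.514 and 0.885). Without basal replicate 4, which does not lean to GC-rich transcripts, Insr passed at both rates (0.68 and 0.58, adjusted p = 0.00924 and 0.0334) and Igf1r at the low rate (0.71, adjusted p = 0.0136). Leaning basal libraries made up a larger share of that fit. Basal replicate 5, a GC-leaning library, had 2.88 CPM of Irs1 (others 14.1 to 14.6) and 21.5 of Irs2 (58.3 to 73.2), and without it Irs1 had 0.22 and 0.20 and Irs2 -0.41 and -0.26. In the hippocampus Insr had 0.00 and 0.23, Igf1r 0.40 and 0.25, Irs1 0.14 and -0.03 and Irs2 -0.05 and 0.17. In the nucleus accumbens Insr had -0.07 and -0.16, Igf1r 0.00 and -0.22, Irs1 -0.09 and -0.22 and Irs2 0.17 and 0.01 (adjusted p from 0.917 to 1 in both tissues).

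Whether the 3 tissues differed in their response was tested as an interaction of tissue and infusion. At the low rate the smallest p belonged to Akap10, an anchoring protein of protein kinase A, with log2 fold changes of 1.04 in the hypothalamus, -0.03 in the hippocampus and -0.17 in the nucleus accumbens. Mal had 0.41, 0.89 and -0.17, Foxj1 -0.43, 1.78 and -0.25, Ppfibp2 -0.09, 0.75 and -0.47, and Sh2b2, an adaptor of the insulin receptor, -0.37, 1.04 and -0.56 (adjusted p = 0.131 for each). At the high rate Ttll3, a tubulin glycylase, had -0.84, 0.35 and -0.06, Nhlrc2 0.83, 0.80 and -0.39, and Nemp2 0.64, 0.46 and -0.33. Adra1a, an adrenergic receptor, had 1.28, 0.60 and -0.48 and Morn2 -1.09, 0.48 and 1.05 (adjusted p = 0.461 for each of the 5). The model takes the 52 libraries as independent, although the labels do not say whether tissues came from the same mice, and with the tag run as a block it also called 0 genes at both rates. By edgeR 0 of 14985 genes differed at either rate, with 2580 and 1592 at an unadjusted p under 0.05 where chance gives 749. The counts of called genes above are thus not shown to differ between tissues. By comparison, limma-voom called 0 at both rates and DESeq2 45 and 0. Without low replicate 4 of the hippocampus the count at the low rate was 22, and without low replicate 2 it was 1. No gene was called in 2 tissues, where 0 are shared by independent lists when 2 of the 3 tissues have no calls, and log2 fold changes correlated across genes at r between -0.337 and 0.152.

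The leading genes lie, in GRCm38 coordinates, at chromosome 18, 71253634 to 72351069 for Dcc (ENSMUSG00000060534) and chromosome 5, 28071363 to 28078662 for Insig1 (ENSMUSG00000045294). Others lie at chromosome 17, 33773750 to 33781830 for Angptl4 (ENSMUSG00000002289), chromosome 2, 127633226 to 127656695 for Mal (ENSMUSG00000027375) and chromosome 8, 3122061 to 3279617 for Insr. Each is annotated as a protein-coding gene, and counts cover the gene as a whole.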

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

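The tests of technical explanations and the bounds used to read them were chosen after the results had been seen, as were the splits of the samples; the criterion for a library far from its group was fixed beforehand. That criterion, Dixon's, asks whether the highest or lowest library is separated from the nearest other one by too large a part of the range. It was met in 31 of 330 groups of values, where chance gives 16.5 (about 1 in 20).

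In the hypothalamus, low replicate 2, the library whose regional score was not the highest, stood apart in 5 genes. It had 58.8 CPM of Zfp871 (others 13.9 to 25.7), 93.7 of Lnpep (12 to 25.5), 49.7 of Hsd17b7 (22.1 to 29.9), 147 of the glial connexin Gjc3 (73.3 to 98.8) and 60.3 of Cp (23.4 to 37.1). High replicate 3, which lacked Hcrt and Pomc, had 22.1 CPM of Crym (4.69 to 6.04), 40.6 of Ngfr (7.36 to 12) and 7.1 of Icam1 (3.4 to 3.87). High replicate 5 had 15.4 CPM of Chrnb3 (0.169 to 2.27) and 114 of Insr (135 to 143). Basal replicate 4 had 9.05 CPM of Lnpep (2.21 to 3.61) and 24.7 of Kcnma1 (10.6 to 13.2), and basal replicate 5 had 2.88 of Irs1 (14.1 to 14.6) and 21.5 of Irs2 (58.3 to 73.2). Gpi1 was 439 CPM in low replicate 1 (301 to 351) and 318 in high replicate 1 (348 to 359), and Ccdc153 was 5.16 in high replicate 2 (1.7 to 2.49).

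In the hippocampus, low replicate 5 stood apart in myelin and neuronal genes, with 9100 CPM of Mbp (others 2610 to 3420), 2560 of Mobp (997 to 1460), 71.6 of Bhlhe22 (87.9 to 96.5), 46.2 of Dsp (110 to 147) and 4.2 of Irs1 (16 to 20.3). High replicate 5 had 56.5 CPM of the choroid plexus gene Folr1 (0.598 to 13.6), high replicate 1 had 89.4 of Arrdc2 (27.3 to 47.2), and high replicate 2 had 224 of Calb1 (108 to 143). Among basal libraries, replicate 2 had 208 CPM of Calb1 (120 to 153) and replicate 6 had 19.1 of Tac2 (1.17 to 4.06). In the nucleus accumbens, basal replicate 2 had 770 CPM of Pde10a (489 to 580), low replicate 1 had 27.6 of Adgrl4 (43.8 to 52.3), high replicate 2 had 10.7 of Ccdc159 (12.5 to 13.6), and high replicate 5 had a total of 8280000 counts (3490000 to 4980000).

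The first pattern weighed is the set of called genes in the hypothalamus. With the GC and length lean of each library as covariates, the log2 fold changes of the 760 genes called at the low rate kept a median of 0.695 of their size (quartiles 0.568 to 0.834), and 0.557 (0.408 to 0.703) without the GC-leaning libraries, whereas the 26 called at the high rate kept 0.94 (0.835 to 1.02) and 0.819 (0.752 to 0.918). For the high-rate genes the lean as the whole cause is not excluded, since they were chosen by their change in the same libraries and the removal left 2 basal ones. For the low-rate genes its part cannot be told apart from insulin, because 3 of 5 basal and 0 insulin libraries lean to GC-rich transcripts. The drop to 92 and 3 calls came with smaller changes and with fewer libraries or degrees of freedom. Leaving out basal replicate 3 or 4, which do not lean, instead raised the calls to 2567 and 3171 at the low rate and to 613 and 1861 at the high rate. The libraries lacking a peptide are argued against as the whole cause, since without them the genes kept 1.01 (0.876 to 1.11) of their change at the low rate and 0.983 (0.941 to 1.04) at the high rate. A graded difference in dissection was not tested. In the low libraries kept, Pomc was 8.3, 6.7 and 6.98 CPM, below the 10.6 to 33.3 of basal libraries, and in the high ones 14.5, 13.9 and 14.7. By the same measure a batch by tag range alone is argued against as the whole cause (0.864, quartiles 0.802 to 0.925, and 0.911, 0.868 to 0.968). The tag range and the lean are not separate explanations, however. Leaning basal replicates 1 and 2 lie in the lowest range, which holds 0 high libraries of the hypothalamus. A preparation batch that follows both the lean and the infusion was not tested and is not excluded. All these genes were chosen in the same libraries, which favours kept changes. An effect of insulin remains an open hypothesis, as does any difference between the mice or preparations that the labels do not record.

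The second pattern is the lower ribosomal protein and respiratory chain lists in the hypothalamus, which may come from the GC lean. Without the GC-leaning libraries the medians at the high rate turned to 0.39 (quartiles 0.17 to 0.59) for ribosomal and 0.45 (0.14 to 0.57) for respiratory chain genes, a result that rests on 2 basal libraries. Without the libraries lacking a peptide they stayed at -0.54 (-0.69 to -0.34) and -0.55, which argues against those libraries as the cause. A graded difference in dissection was not tested. An effect of insulin on these lists was not separated from the lean.

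The third pattern is the higher oligodendrocyte list in the hippocampus. Over its markers, a score per library was higher than in every basal library in 6 of 6 low libraries (difference 0.82 on the log2 scale) and 6 of 6 high libraries (0.57), which restates the list result in the same libraries and is no separate test. With scores of choroid plexus, ependyma and thalamus as covariates the median of the list at the low rate was 0.44 (quartiles 0.39 to 0.49) against 0.89 as reported, and without the GC-leaning libraries it was 0.67 (0.61 to 0.81). Neither neighbouring tissue nor the lean was excluded by these values. White matter itself was not tested, since the scores hold no marker of it and oligodendrocytes are its own cells; insulin acting on oligodendrocytes stays an untested alternative.

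Random splits of the same samples into groups of the same sizes were run for each comparison. For the 26 genes called in the hypothalamus at the high rate the splits argue against chance: 1 of 100 splits, the real one, reached 26, and the highest other gave 3. With 99 other splits that is the lowest share possible, and no correction was made for the number of comparisons. Nor can such splits separate insulin from the lean of the basal libraries. Libraries were exchanged freely across tag runs, some of which hold a basal and a high library. With the tag run as a block 0 genes were called, although all 26 kept their direction and a median of 0.92 of their change. In 1 fit of all 52 libraries 0 were called, and without the GC-leaning libraries 1. For the 760 genes at the low rate chance cannot be excluded: 7 of 100 splits, the real one included, called as many, and the highest other gave 4610, several times the real count, which points to a structure of the samples. All 6 of those other splits put the 3 GC-leaning basal libraries on 1 side, as did 22 of the 99 other splits. Where 0 genes were called, 100 of 100 splits, or 50 of 50 for the differences between tissues, reached that count by definition, so the splits decide nothing there. The highest other counts there were 15 for the hypothalamus between rates, 65, 269 and 3 for the hippocampus (low, high and between rates), 240, 1 and 190 for the nucleus accumbens, and 1431 and 2795 for the differences between tissues at the low and high rate.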

How the results depend on the processing

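The alternatives on GC lean, GC and length offset, GC-leaning libraries and libraries lacking a peptide were chosen after the data were seen; unless stated, the cause of a change was not tested. The replicate numbers only follow the order of the libraries and were not used for pairing; the tag runs, several of which hold libraries of every infusion of a tissue, served as the block. The 760 genes called in the hypothalamus at the low rate became 1678 with DESeq2, 2334 at a threshold of 0.1, 29 with the tag range and 16 with the tag run as a term, 391 with 1 surrogate variable, 92 with lean covariates, 126 with a GC and length offset, 3 without GC-leaning libraries, 24 without libraries lacking a peptide and 22 with only the 2 groups, the last 3 with fewer libraries in the fit. Of the 760, the direction was kept by 760 with either tag term or lean covariates, 732 with the offset and 754 without GC-leaning libraries. Both these genes and the 26 at the high rate were chosen in the same libraries, which favours a kept direction. The 26 at the high rate became 50 with no filter, 359 with DESeq2, 53 with limma-voom, 199 at 0.1, 5 with the tag range, 0 with the tag run, 1 without GC-leaning libraries, 9 without libraries lacking a peptide, 17 with only the 2 groups and 0 in 1 fit of all 52 libraries; the direction of all 26 was kept under both tag terms, both GC corrections and both removals.

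The 0 calls of the hippocampus at the low rate became 38 with DESeq2, 7 with 1 surrogate variable, 17 with lean covariates, 23 with the offset and 101 in 1 fit of all libraries, and those of the tissue difference at the low rate 45 with DESeq2. The overlap of 26 genes between rates became 193 at 0.1 and 3 with the basal libraries split, and the 73 list calls became 0 with an estimated correlation and 4 with fry (cholesterol in the hypothalamus at both rates, oligodendrocytes and fatty acid synthesis in the hippocampus at the low rate). Leaving out 1 library gave 52 (without basal replicate 2) to 3171 (basal replicate 4) calls in the hypothalamus at the low rate, 6 to 1861 (the same libraries) at the high rate, 0 to 22 tissue differences at the low rate (22 without hippocampus low replicate 4), and 61 to 87 list calls (without hippocampus low replicate 5 and 4); the other counts stayed at 0.

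Directions that turned without GC-leaning libraries were those of Tceal3 (log2 0.05) and Rps3 (0.03) at the low rate in the hypothalamus, and there of ribosomal proteins (adjusted p = 0.000176 low, 2.24e-08 high), respiratory chain (5.79e-09 high), insulin signalling (0.705 low, 0.564 high) and glycolysis (0.949 high). With 1 surrogate variable ribosomal proteins turned in the hypothalamus (0.974 low, 0.0778 high) and in the hippocampus between rates (0.895), and respiratory chain in the hypothalamus at the high rate (0.00254). With lean covariates ribosomal proteins turned in the nucleus accumbens at the high rate (0.876). Of the 73 list calls, those lost with no turn in direction were 3 with the tag range, 6 with the tag run as a block, 14 with 1 surrogate variable, 25 with lean covariates, 24 without GC-leaning libraries and, of the 26 in the hypothalamus, 14 without libraries lacking a peptide. With DESeq2 size factors all 73 list calls and all named called genes kept their call. The depth of 2453412 to 8279612 counts limits low genes most, and in simulated data 1.5-fold changes were recovered for 24% of genes in the hypothalamus at the low rate.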

Other observations

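The genes below were chosen after their values were seen. Genes that respond to fasting and to FOXO factors, which insulin holds out of the nucleus, moved in both directions in the hypothalamus, and so did not shift as a list. Camera gave adjusted p = 0.803 at the low and 0.5 at the high rate, whereas fry's test for change in either direction gave adjusted p = 8.91e-06 and 0.000456 over 21 measured members. That test was not particular to this list: it called 12 of 40 lists at the low rate, among them cholesterol (adjusted p = 0.000484) and potassium channel genes (adjusted p = 0.00312), and 2 at the high rate, the other being cholesterol (adjusted p = 0.00467). Sesn3, a FOXO target that restrains mTOR complex 1, rose from 17.8 ± 5.93 CPM (SD, n = 5) to 58.5 ± 8.16 (SD, n = 6; log2 fold change 1.74, adjusted p = 6.7e-05 by edgeR) and 56.1 ± 7.3 (SD, n = 5; 1.68, adjusted p = 0.000351). Angptl4, another fasting-induced gene, fell by 1.11 on the log2 scale at both rates (adjusted p = 0.0101 and 0.0369). Adjusted over the list alone, 1 rose and 3 fell at the low rate, and 1 rose and 1 fell at the high rate. Txnip, a glucose-responsive inhibitor of thioredoxin, had -0.51 at the low rate (adjusted p = 0.0665) and Cited2, a co-regulator of hypoxia responses, -0.29 (adjusted p = 0.0713). In the hippocampus and nucleus accumbens the same test gave adjusted p from 0.86 to 1 at both rates, and whether the tissues differ in this list was not tested.

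Ryr3, a calcium release channel of the endoplasmic reticulum, was among the 3 genes called at the low rate without the GC-leaning libraries, with Dcc and Sesn3. It rose from 41.6 ± 8.37 CPM (SD, n = 5) to 102 ± 18 (SD, n = 6; log2 fold change 1.30, adjusted p = 0.000404 by edgeR) and to 92.5 ± 12.7 (SD, n = 5; 1.16, adjusted p = 0.00302).

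Of the 40 lists tested, 12 were called in 0 comparisons by camera with the preset correlation: pyruvate dehydrogenase and the TCA cycle, pentose phosphate, mitochondrially encoded genes, receptors of appetite and metabolic hormones, glutamate receptors, synthesis and transport of GABA and glutamate, SNARE and synaptic vesicle genes, the FOXO list, the circadian clock, astrocytes, neurons, and cortical and hippocampal pyramidal neurons.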
